A study of Homo sapiens with 9 samples.

How the data were processed

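The deposited gene table holds RNA sequencing of 9 libraries of the human leukaemia line MOLM-13, 3 with a scrambled hairpin and 3 with each of 2 hairpins against TICAM1. Per the labels' protocols, total RNA was sequenced on a DNBSEQ instrument. Per the submitters' processing notes the genome was GRCh37 p13, but the deposited table gives GRCh38 chromosome accessions for 14806 of its 15810 genes, so coordinates are given on GRCh38. Of the gene identifiers, 15759 were found in the reference annotation, and 51.8% of gene starts were identical to it. The aligner and the quantification tool are not given in the sources used here.

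The table lists 15810 genes, all of type mRNA. Per the file headers it gives read counts, which the authors deposited in the form of expected counts, that is estimated reads per gene without normalization: 12.37% to 14.55% of the values in a library were not whole within 0.001. The authors also deposited TPM, the length-scaled share of each gene's transcripts, for each library, which sum to 995253 to 997385. The authors' deposited table further holds log2 fold changes of each hairpin against Scramble, computed per the file headers in the comparison of the control with each hairpin. The matching p-values and q-values are from DESeq2 per the file headers of the authors' table, and the p-value is missing for 330 genes with shRNA 1 and 342 with shRNA 2. The mitochondrially encoded genes are not listed, so their list was not analysed here.

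Samples were grouped by their treatment label. The ninth sample has a title that names a hairpin 3 and a label that names shRNA 2, and it was kept with shRNA 2. Expected counts were rounded to whole numbers. edgeR 4.0.16 in R 4.3.3 filtered genes with filterByExpr (11984 kept), scaled libraries by TMM and fitted a quasi-likelihood model with 1 coefficient per group over all 9 libraries (6 residual degrees of freedom). Tests were two-sided, with Benjamini-Hochberg correction over all genes kept and a threshold of 0.05 on the adjusted p. The contrasts were each hairpin against Scramble, the average of both hairpins against Scramble, and shRNA 2 against shRNA 1. Standard errors are those of the fitted log2 fold change, and CPM are scaled by TMM. These tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

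Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated and with fry. Lists with at least 5 tested members were tested, 29 in all, and the correction was over these. Counts of called members are given over all genes and adjusted over the list alone. TICAM1 was tested in addition by an exact two-sided permutation of its CPM.

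Genes named are TICAM1; for each single comparison and for shRNA 2 against shRNA 1, the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups; up to 12 genes in each direction called with both hairpins and without overlap between the 6 knockdown and 3 Scramble libraries; and for each list up to 4 members with the smallest adjusted p in the average, with any member already named. Genes without a symbol were skipped. Some genes that meet the rule are not reported here.

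The replicate number in the titles was checked as a pairing by correlating each library's deviation from its group mean between groups. Libraries of shRNA 1 and Scramble with the same number correlated at 0.18, 0.14 and 0.19, those of shRNA 2 and Scramble at 0.08, -0.02 and 0.18, and those of both hairpins at 0.73, 0.57 and 0.87. The correlations with Scramble are weak: Scramble library 1 and shRNA 1 library 2, which differ in number, also correlated at 0.14. Values with the number as a block are given beside those of shRNA 1 against Scramble and of shRNA 2 against shRNA 1. The other blocked counts are given with the dependence on processing.

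The fit was tested on simulated data with the spread of these libraries. Of 50 genes changed 2-fold, 62% were recovered with shRNA 1, 56% with shRNA 2 and 74% in the average, and of 50 changed 4-fold, 98%, 96% and 98%. Of 11686 unchanged genes 6, 9 and 9 were called in these comparisons. The list test made a false call in 2 of 20 simulations of independent genes, but other splits of the real libraries called a median of 14 of 29 lists with the preset correlation. Depth differed by at most 1.31 times between libraries.

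Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), the replicate number as a block, only the groups compared, a 2-fold minimum, and each library left out in turn. Added later were a term for the third libraries, the first and second libraries alone, the estimated correlation combined with these or with the block, and a permutation of list means. Libraries were not compared with technical duplicates, as there are none.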

Results

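RNA was sequenced from MOLM-13 cells, an established acute myeloid leukaemia line that carries an MLL fusion and an internal tandem duplication of FLT3. The cells had received lentiviral vectors with a scrambled hairpin (Scramble, n = 3 libraries) or with 1 of 2 short hairpin RNAs against TICAM1 (shRNA 1 and shRNA 2, n = 3 libraries each). TICAM1 encodes TRIF, the adaptor through which Toll-like receptors 3 and 4 signal to interferon regulatory factors, NF-kappaB and cell death kinases, and the stated purpose was to learn what it does in this leukaemia. The Scramble libraries held 18692118, 16462564 and 15171642 reads assigned to genes, those of shRNA 1 held 17639654, 16826303 and 15925334, and those of shRNA 2 held 16909001, 14249345 and 15831989. In each library 13748 to 14331 genes had at least 1 read, and 11984 genes passed the count filter. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these samples. The third library of shRNA 2 has a title that names a hairpin 3 while its treatment label names shRNA 2, and it was grouped by the treatment label.

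TICAM1 was lower in all 6 knockdown libraries than in any Scramble library. The gene (NCBI gene 148022) is placed on chromosome 19 from 4815932 to 4831712, on the GRCh38 chromosome sequence that the deposited table names. It was counted at 21.2, 19.3 and 22.1 CPM (counts scaled to library size by TMM) in Scramble libraries 1, 2 and 3, at 16.1, 14.5 and 9.66 CPM in those of shRNA 1. With shRNA 2 it was at 14.5, 14.3 and 11.8 CPM. The means were 20.9 ± 1.43 CPM (SD, n = 3) in Scramble, 13.4 ± 3.35 CPM (SD, n = 3) with shRNA 1 and 13.5 ± 1.49 CPM (SD, n = 3) with shRNA 2. The log2 fold change was -0.64 ± 0.19 (SE) for shRNA 1 and -0.63 ± 0.19 for shRNA 2, which left 64.3% and 64.8% of the Scramble level. An exact two-sided permutation test of CPM gave p = 0.1 for each hairpin, the smallest value that 3 against 3 libraries allow. For the 6 knockdown libraries against the 3 Scramble libraries the exact permutation p was 0.0119, also the smallest possible. That permutation treats all libraries as exchangeable and the 6 knockdown libraries as independent. Across genes, libraries of both hairpins with the same number deviated together, so this p may overstate the evidence. Corrected over all genes, edgeR's quasi-likelihood test did not pass 0.05 for shRNA 1 (adjusted p = 0.21), shRNA 2 (adjusted p = 0.19) or their average (log2 fold change -0.63 ± 0.16, adjusted p = 0.093). The average passed with the replicate number as a block (adjusted p = 0.03), with DESeq2 (adjusted p = 0.015) and in the libraries numbered 1 and 2 alone (log2 fold change -0.47, adjusted p = 0.01). The range over the alternatives was 0.01 to 0.21. Within the libraries that share a number, the log2 difference was -0.47 for number 1, -0.42 for number 2 and -1.04 for number 3. The authors' deposited table gives log2 fold changes of -0.65 (q = 0.23) and -0.64 (q = 0.055) for the same gene.

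**Figure D1:**
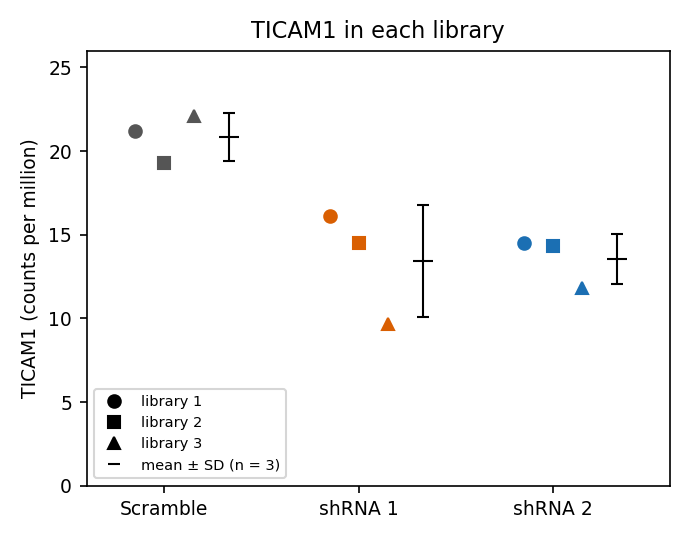
TICAM1 in each library, in CPM after TMM scaling; symbols mark the library number, and the bar beside each group is the mean ± SD of its 3 libraries. The 6 knockdown libraries lie between 9.66 and 16.1 CPM and the 3 Scramble libraries between 19.3 and 22.1 CPM.

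The libraries numbered 3 stood apart from those numbered 1 and 2 in every group. The first principal component of log2 CPM (43.8% of the variance) placed the knockdown libraries 1 and 2 between 26.1 and 34.1, Scramble libraries 1 and 2 at -7.9 and -12.5, and the third libraries between -41.1 and -30.2. The second component (21%) separated the third Scramble library, at 40.0, from the third knockdown libraries, at -25.6 and -33.6. Across 9423 genes with a mean log2 CPM above 3, the fold changes of a hairpin in set 1 and in set 2 correlated at 0.69 to 0.77 between sets, whereas those of sets 1 and 2 correlated with those of set 3 at 0.02 to 0.20. Genes are not independent replicates, and each set holds 1 Scramble library. The chi-square per degree of freedom between libraries 1 and 2 was 17.7 in Scramble, 8.4 with shRNA 1 and 6.6 with shRNA 2. Between either of these and library 3 of the group it was 55.6 to 87.9. Results in the libraries numbered 1 and 2 alone, that for TICAM1 included, rest on this closer spread. The third libraries were left out after the result was seen, so such counts may be too high. For each gene list tested in the average, values within the 3 numbered sets stand beside the pooled ones below, as they do for some of the genes.

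**Figure D2:**
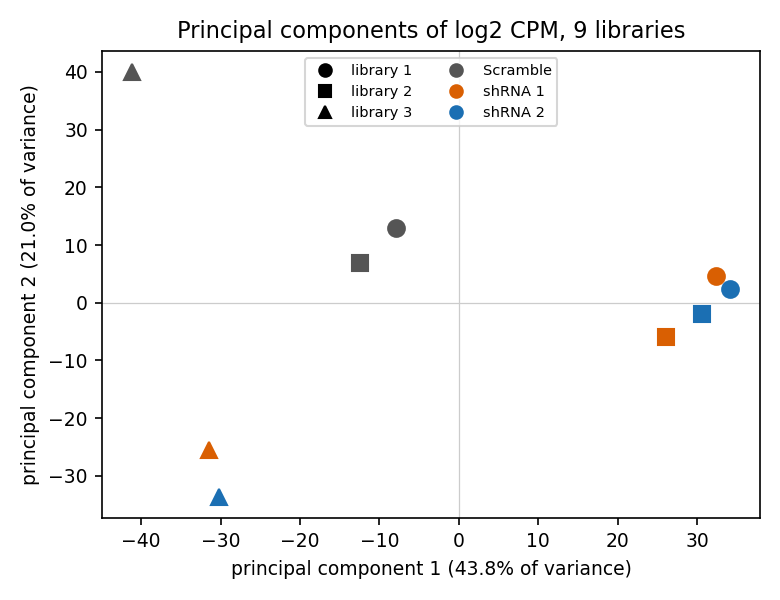
Principal components 1 (43.8% of the variance) and 2 (21%) of log2 CPM in the 9 libraries; colour marks the group and the symbol the library number. The libraries numbered 3 lie below -30 on the first component, apart from the others of their group.

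Cells with shRNA 1 were compared with Scramble to find the transcripts that this hairpin changed. ADM, which encodes the hypoxia-induced vasodilator peptide adrenomedullin, rose from 3.53 ± 1.31 CPM (SD, n = 3) to 27.5 ± 8.84 CPM (SD, n = 3), a log2 fold change of 2.96 ± 0.37 (SE). With both hairpins together ADM differed from Scramble by 3.24, 3.47 and 1.82 in sets 1, 2 and 3. ADAMTS14, a protease that trims procollagen, rose by 2.62 ± 0.28 on the log2 scale, and TBC1D30, a GTPase-activating protein for Rab proteins, by 1.83 ± 0.22. PIK3R6, a regulatory subunit of phosphoinositide 3-kinase gamma, rose by 1.60 ± 0.15 and H2AC18, a histone H2A gene, by 1.39 ± 0.18. ANLN, an actin-binding protein of the cleavage furrow, was the 1 gene that fell, from 69.3 ± 3.77 to 41.0 ± 0.719 CPM (SD, n = 3 each; log2 fold change -0.76 ± 0.10). In total 8 genes passed, 7 higher and 1 lower. The edgeR adjusted p lay between 0.018 and 0.046 for the genes named here. Each had no overlap between the CPM of the groups, which chance gives in 10% of genes. The rule for naming genes required this, so it adds no support of its own. Gene lists called with shRNA 1 numbered 18 of 29 by camera with a preset correlation, 11 higher and 7 lower. With an estimated correlation 2 were called, the histones (adjusted p = 0.017) and interferon gamma and antigen presentation (adjusted p = 0.036). With the replicate block and an estimated correlation 4 were called, these and the lists of NF-kappaB targets and of monocyte and macrophage differentiation (adjusted p = 0.047 for each). The list of the MLL fusion and stemness programme was lower with shRNA 1 (median log2 fold change -0.13, adjusted p = 0.046, and adjusted p = 0.54 with an estimated correlation; 0 of 23 members called over all genes or adjusted over the list alone). That call was lost without Scramble library 3 (0.72) or shRNA 1 library 1 (0.34). Without Scramble library 3 the list calls for Toll-like receptor and TRIF signalling (0.14), monocyte differentiation (0.07), p53 targets (0.16), MYC targets (0.077), lysosome (0.47) and DNA repair (0.47) were lost too. Without shRNA 1 library 1 those for p53 targets (0.068) and lysosome (0.085) were lost, and without Scramble library 1 that for ATF4 targets (0.077). The adhesion and migration list was called higher with the replicate block (adjusted p = 0.0032 against 0.051 without it, and adjusted p = 0.23 with the block and an estimated correlation). The count of genes was 0 without Scramble library 1, 2 or 3, shRNA 1 library 1 or 2, or shRNA 2 library 2 (edgeR; 873 to 1774 genes at an unadjusted p under 0.05, other tools not run on these). It was 2 without shRNA 2 library 1 and 15 without shRNA 1 library 3. It was 610 (352 higher, 258 lower) with the replicate number as a block, 423 with DESeq2, 1 with limma-voom and 2529 in the libraries numbered 1 and 2 alone. The authors' deposited table lists 203 genes with q under 0.05 (144 higher, 59 lower).

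The same question was asked of shRNA 2. MPEG1, the pore-forming perforin-2 of macrophages, rose from 6.71 ± 3.6 to 52.2 ± 2.66 CPM (SD, n = 3 each; log2 fold change 2.95 ± 0.42), and HPD, an enzyme of tyrosine breakdown, rose by 3.17 ± 0.46 on the log2 scale from 1.35 ± 0.683 CPM. HLA-DMA, which loads peptides onto class II molecules, rose by 2.06 ± 0.30 and CD74, the invariant chain that chaperones them, from 217 ± 22.8 to 490 ± 56.7 CPM (SD, n = 3 each; 1.17 ± 0.14). LY96, the MD-2 partner of Toll-like receptor 4, rose by 2.90 ± 0.40 from a low level of 0.412 ± 0.201 CPM. GATA2, a transcription factor of blood progenitors, fell from 112 ± 20.2 to 45.1 ± 5.45 CPM (SD, n = 3 each; -1.32 ± 0.17). ADM (2.78 ± 0.37) and ADAMTS14 (2.08 ± 0.27) rose as well. In total 21 genes passed, 20 higher and 1 lower. The edgeR adjusted p was 0.047 for each gene named in these sentences, with no overlap between the CPM of the groups. Gene lists called with shRNA 2 numbered 20 of 29 by camera with a preset correlation, 12 higher and 8 lower. With an estimated correlation 2 were called, again the histones (adjusted p = 0.016) and interferon gamma and antigen presentation (adjusted p = 0.033). Fatty acid synthesis and oxidation was lower (median -0.15, adjusted p = 0.046, and adjusted p = 0.52 with an estimated correlation; 0 of 32 members called over all genes or adjusted over the list alone). That call was lost without Scramble library 1 (0.43) or 2 (0.095), shRNA 1 library 3 (0.051) or shRNA 2 library 1 (0.11). Without Scramble library 3 the list calls for granulocyte maturation (0.076), p53 targets (0.14), lysosome (0.4) and DNA repair (0.27) were lost. Without shRNA 2 library 1 those for granulocyte maturation (0.068) and lysosome (0.068) were lost, and without shRNA 2 library 2 those for p53 targets (0.074) and lysosome (0.074). The count of genes was 0 without Scramble library 1 or 2, shRNA 1 library 1 or 2, or any library of shRNA 2 (edgeR; 1126 to 2514 genes at an unadjusted p under 0.05, other tools not run on these), and 36 without Scramble library 3. It was 536 with DESeq2, 4 with limma-voom and 2875 in the libraries numbered 1 and 2 alone. The authors' deposited table lists 249 genes with q under 0.05 (176 higher, 73 lower).

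Genes that both hairpins moved the same way are less open to effects of a single hairpin sequence. ADM, ADAMTS14, TBC1D30, PIK3R6 and H2AC18 rose with each hairpin, as did KCNQ3, a subunit of a voltage-gated potassium channel (1.27 ± 0.17 and 1.31 ± 0.17 on the log2 scale), and TMEM156, a transmembrane protein of unclear function (0.99 ± 0.10 and 0.94 ± 0.10; adjusted p = 0.018 to 0.047 for the 7 genes). These 7 genes were the whole overlap of the calls, all higher. Independent lists would share 0.012 higher and 1e-04 lower genes, and 20 simulations of unchanged groups with shared Scramble libraries gave 0 in each. Both baselines are incomplete. The first ignores the shared Scramble libraries, and the simulations drew each library independently, without the numbered sets. In these 7 genes the 6 knockdown libraries lay above all 3 Scramble libraries, as the rule for naming them required. H2AC18 shares nearly all of its sequence with other histone genes, so its reads may be split among copies and its level is uncertain. Across 11984 genes the fold changes of both hairpins correlated at Pearson 0.92 and Spearman 0.89 with the same sign in 87.2% of genes. Unchanged groups simulated against the same Scramble libraries gave 0.498, 0.466 and 66.7%. The covariance was 0.205 against 0.0558 in the simulation. In the real libraries, those of both hairpins with the same number deviated together at 0.73, 0.57 and 0.87. The simulation left this out, so its values may be too low as a baseline. The overlap was 0 without any single library (edgeR; 723 to 1335 genes at an unadjusted p under 0.05 with both hairpins) except shRNA 1 library 3, whose omission gave 10. It was 324 genes with DESeq2, 1 with limma-voom and 2106 in the libraries numbered 1 and 2 alone. The same 7 were among the 324, and limma-voom called 1 of them.

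The average of both hairpins against Scramble used all 9 libraries. Its test counted every knockdown library as independent, although those of both hairpins with the same number deviated together at 0.73, 0.57 and 0.87. The standard errors of the average may therefore be too small and its count of genes too high. CD74 rose by 1.05 ± 0.13 on the log2 scale, HLA-DMA by 1.98 ± 0.27 and MPEG1 by 2.47 ± 0.38. So did the inhibitory receptor gene LILRB2 by 2.08 ± 0.38, the adhesion molecule gene ICAM1 by 1.34 ± 0.25 and LY96 by 2.55 ± 0.37. ANLN fell by 0.68 on the log2 scale (SE 0.08) and MKI67, the proliferation antigen, from 237 ± 21.3 CPM in Scramble to 143 ± 12.7 and 149 ± 10.5 CPM with the hairpins (SD, n = 3 each). GATA2 fell by 1.19 on the log2 scale (SE 0.14). In sets 1, 2 and 3 the log2 difference was -1.41, -1.47 and -0.67 for GATA2, 2.22, 2.13 and 3.53 for MPEG1, 1.41, 1.80 and 2.81 for HLA-DMA, and 0.92, 1.41 and 0.82 for CD74. It was 1.80, 3.11 and 2.13 for LY96, 2.08, 2.39 and 1.32 for LILRB2, 1.01, 1.16 and 2.17 for ICAM1, and -0.57, -0.68 and -0.86 for MKI67. In total 146 genes passed edgeR's test, 89 higher and 57 lower. The knockdown and Scramble libraries did not overlap in any of them, a separation that 1 of 84 splits gives in each direction if all libraries are exchangeable. These genes were chosen by a test on the same values, so the separation adds no support of its own. The adjusted p was 0.021 to 0.046 for the genes named here. The count fell to 0 without Scramble library 2, shRNA 1 library 1 or 2, or shRNA 2 library 1 (1620 to 1952 genes at an unadjusted p under 0.05, other tools not run on these), to 3 without Scramble library 1 and to 5 without shRNA 2 library 2. It was 888 with DESeq2, 135 with limma-voom and 3516 in the libraries numbered 1 and 2 alone, and the 888 and the 3516 include all 146. The 3516 rests on the closer spread of those libraries.

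**Figure D3:**
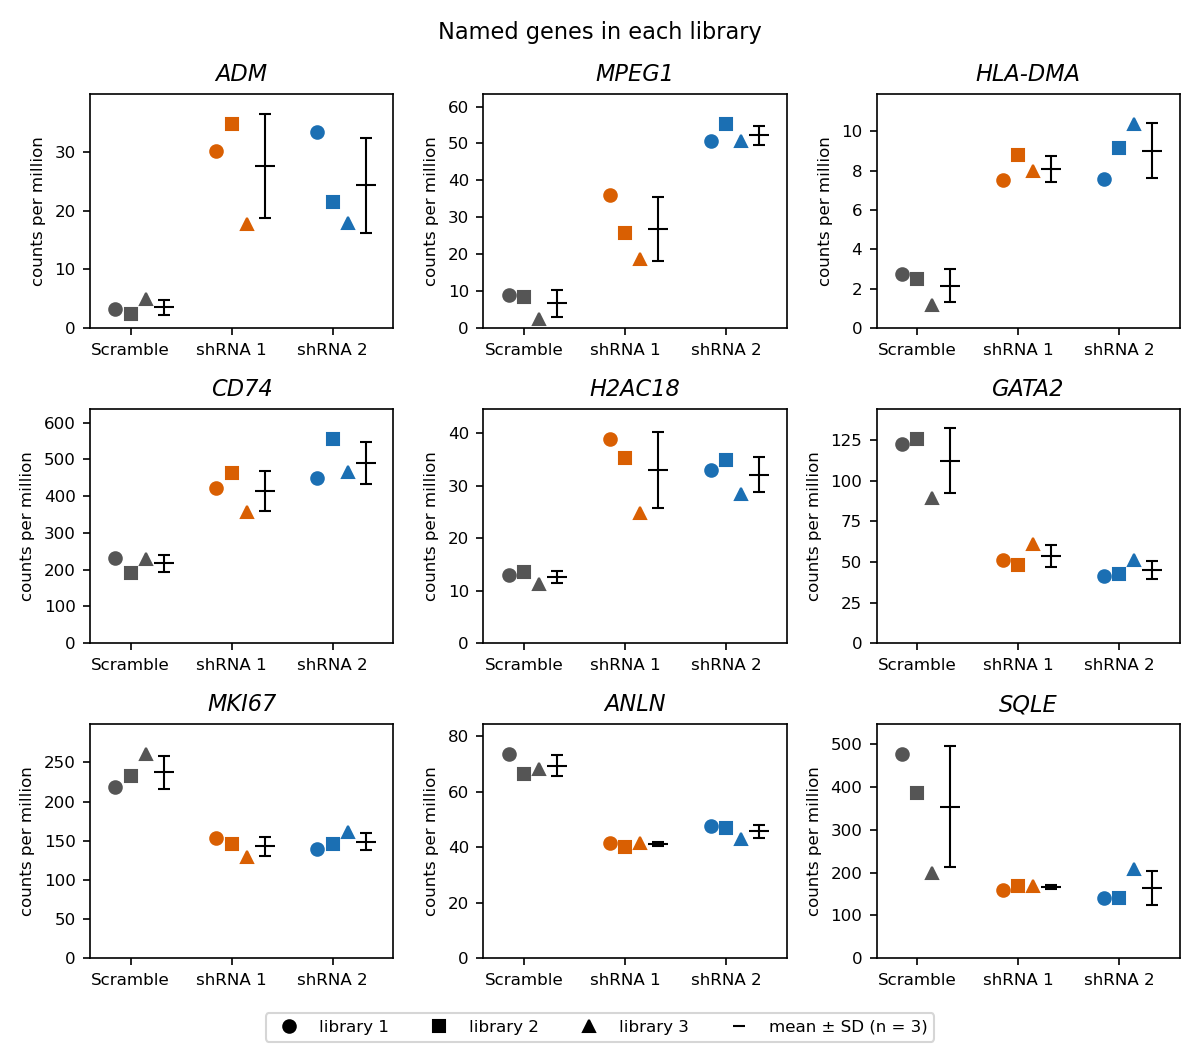
CPM of 9 named genes in each library, on linear axes from 0; symbols mark the library number, and the bar beside each group is the mean ± SD of its 3 libraries. For CD74 and MPEG1 the knockdown libraries lie above all Scramble libraries; for SQLE, whose adjusted p was 0.063, the third Scramble library lies below 1 of the knockdown libraries.

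Of 29 gene lists with at least 5 tested members, camera with a preset correlation of 0.01 called 19 in the average, 12 higher and 7 lower. With an estimated correlation 2 remained, histones and interferon gamma and antigen presentation. The directional test of fry called these and G2/M and mitosis (adjusted p = 0.00086, 0.00086 and 0.014). Among 100 splits of the 9 libraries, 16 called at least 19 lists, and the splits other than the real one called a median of 14, so a call with the preset correlation is weak evidence by itself. An exact permutation test of each list's mean level over 84 splits, added after the list tests were seen, left no list past 0.05 after correction (smallest adjusted p = 0.069; 0 of 29 lists, with 8 at an unadjusted p under 0.05, against 19 by camera and 3 by fry). That test gave its smallest p, 0.0119, for 5 of the lists: interferon gamma and antigen presentation, G2/M and mitosis, immediate early genes, glycolysis and hypoxia, and histones. With 84 splits no smaller p is possible, and 5 of 29 lists at that floor give the adjusted 0.069. The miss after correction therefore does not count against these lists. That test also ignores the numbered sets.

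Cell division genes were lower as a group. In G2/M and mitosis the median log2 fold change was -0.45 (adjusted p = 2.7e-24, and adjusted p = 0.22 with an estimated correlation), 42 of 43 members lay below 0, 6 fell over all genes and 29 adjusted over the list alone. ANLN (-0.68 ± 0.08, SE), MKI67 (-0.70 ± 0.10), the mitotic kinesins KIF2C (-0.76 ± 0.11) and KIF20A (-0.63 ± 0.10) were among the 6. The median was -0.57, -0.35 and -0.44 in sets 1, 2 and 3. G1/S and DNA replication had a median of -0.30 (adjusted p = 3.4e-12, and adjusted p = 0.27 with an estimated correlation), none of 46 members above 0, 1 that fell over all genes, the cell cycle transcription factor E2F3 (-0.41 ± 0.08), and 6 adjusted over the list alone. Its set medians were -0.29, -0.32 and -0.39. DNA damage repair was lower (median -0.16, adjusted p = 0.0035, and adjusted p = 0.53 with an estimated correlation), with the mismatch repair gene MSH6 (-0.56 ± 0.09) as the 1 of 40 members that fell and 3 adjusted over the list alone. In sets 1, 2 and 3 its median was -0.02, -0.10 and -0.24, and it was not called without Scramble library 3 (0.37). Histone genes, most of whose transcripts end in a stem-loop instead of a poly(A) tail, went the other way. Their median was 1.03 (adjusted p = 7.5e-13, and adjusted p = 0.017 with an estimated correlation) and 18 of 19 members tested, out of 38 in the list, lay above 0. The list's level was low, at a mean log2 CPM of 1.29 to 1.62 in Scramble and 2.36 to 2.68 in the knockdown libraries. H2AC18 (1.37 ± 0.16), H2AC8 (1.81 ± 0.26) and H2BC5 (1.46 ± 0.24) rose over all genes, 11 adjusted over the list alone. Histone medians were 0.60, 0.90 and 1.33 in sets 1, 2 and 3, and near-identical copies make the level of single histone genes uncertain.

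The antigen presentation list was higher, while the list for the type I interferon response, a known output of TRIF, was not called. Interferon gamma and antigen presentation had a median of 0.13 and a mean of 0.70 on the log2 scale (adjusted p = 2.5e-05, and adjusted p = 0.036 with an estimated correlation), 19 of 24 members above 0 and 3 that rose over all genes, CD74, HLA-DMA and ICAM1, with 7 adjusted over the list alone. Its set medians were 0.40, 0.30 and 0.42. HLA-DRB1, which shares reads with other class II genes, was at 0.439 ± 0.0934 CPM in Scramble and 7.96 ± 8.19 CPM with shRNA 2 (SD, n = 3 each; average adjusted p = 0.073). The type I interferon list, of which 16 of 40 members were tested, had a median of 0.07 (adjusted p = 0.092, and adjusted p = 0.54 with an estimated correlation), 0 members called over all genes by edgeR and 3 higher adjusted over the list alone. It was called without Scramble library 1 (0.023) or 2 (0.01), and its set medians were -0.14, -0.03 and 0.64. Its mean log2 CPM was 4.10, 4.08 and 3.24 in Scramble libraries 1, 2 and 3, and 3.90 to 4.19 in the knockdown libraries. The higher median in set 3 thus goes with a low level in Scramble library 3. The hallmark set of the interferon alpha response, with 61 members and tested after the data were seen, was called higher (median 0.10, adjusted p = 0.021, and adjusted p = 0.53 with an estimated correlation; set medians 0.11, 0.08 and 0.13). Toll-like receptor and TRIF signalling was higher (median 0.24, adjusted p = 0.00085, and adjusted p = 0.27 with an estimated correlation), with LY96 as the 1 of 37 members that rose and 8 higher and 1 lower adjusted over the list alone. In sets 1, 2 and 3 its median was 0.39, 0.26 and 0.15, and the initiator caspase gene CASP8 (0.86 ± 0.18, adjusted p = 0.059) and the adaptor gene TIRAP (1.09 ± 0.25, adjusted p = 0.071) missed the threshold over all genes.

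Inflammatory and myeloid maturation lists were higher by camera, each without a call once the correlation was estimated. NF-kappaB targets and inflammatory cytokines had a median of 0.56 (adjusted p = 3.3e-07, and adjusted p = 0.28 with an estimated correlation), 28 of 32 members above 0, ICAM1 as the 1 that rose and 5 adjusted over the list alone. Its set medians were 0.62, 0.51 and 0.51. Monocyte and macrophage differentiation had a median of 0.59 (adjusted p = 6.7e-06, and adjusted p = 0.5 with an estimated correlation), MPEG1 and LILRB2 as the 2 of 33 members that rose, 3 adjusted over the list alone, and set medians of 0.47, 0.57 and 0.59. Its mean log2 CPM was lower in the third library of every group: 4.92, 4.88 and 3.63 in Scramble libraries 1, 2 and 3, 5.85, 5.64 and 4.33 with shRNA 1, and 5.68, 5.63 and 4.56 with shRNA 2. Granulocyte maturation had a median of 0.60 (adjusted p = 0.00069, and adjusted p = 0.5 with an estimated correlation) with 0 of 25 members called over all genes by edgeR, 7 higher and 1 lower adjusted over the list alone, and set medians of 0.59, 0.64 and 0.12. Immediate early genes, the first transcripts made after a stimulus, had a median of 0.48 (adjusted p = 0.00013, and adjusted p = 0.27 with an estimated correlation), 0 of 29 members called over all genes, 6 higher and 1 lower adjusted over the list alone, and set medians of 0.58, 0.72 and 0.01. Necroptosis and pyroptosis (median 0.40, adjusted p = 0.00012, and adjusted p = 0.27 with an estimated correlation; set medians 0.48, 0.50 and 0.15) had 0 of 21 members called over all genes and 1 higher adjusted over the list alone. Lysosome and autophagy (median 0.22, adjusted p = 0.00074, and adjusted p = 0.55 with an estimated correlation; set medians 0.33, 0.29 and 0.16) had 36 of 40 members above 0, 0 called over all genes or adjusted over the list alone, and no call without Scramble library 3 (0.42). The adhesion and migration list (median 0.20, adjusted p = 0.039, and adjusted p = 0.55 with an estimated correlation; set medians -0.05, 0.18 and 0.45) held the chemokine receptor gene CXCR4, which rose (1.05 ± 0.17), and the membrane protease gene MMP14, which fell (-0.73 ± 0.13), 1 higher and 1 lower of 29 also adjusted over the list alone. Its call was lost without shRNA 1 library 1 (0.066) or 2 (0.053) or shRNA 2 library 1 (0.056) or 2 (0.059), and its direction turned without Scramble library 3 (0.82), within a range of 0.00022 to 0.82 over single omissions.

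Cholesterol synthesis and uptake had a median of -0.49 (adjusted p = 2.3e-10, and adjusted p = 0.27 with an estimated correlation), with 2 of 25 members that fell over all genes and 13 adjusted over the list alone. In sets 1, 2 and 3 its median was -0.76, -0.67 and 0.01. SQLE, the squalene epoxidase gene, differed by -1.67, -1.32 and -0.08 in sets 1, 2 and 3 and missed the threshold in the average (-1.10 ± 0.24, adjusted p = 0.063). The unfolded protein response and ATF4 targets had a median of -0.23 (adjusted p = 0.00086, and adjusted p = 0.27 with an estimated correlation) with CEBPG (-0.61 ± 0.11), a bZIP partner of ATF4, as the 1 of 39 members that fell and 1 adjusted over the list alone. Its set medians were -0.46, -0.40 and 0.05. MYC targets (median -0.23, adjusted p = 0.00012, and adjusted p = 0.55 with an estimated correlation; set medians -0.42, -0.20 and -0.04) had 41 of 44 members below 0 and 0 called over all genes or adjusted over the list alone. Glycolysis and hypoxia had a median of 0.32 (adjusted p = 1.4e-07, and adjusted p = 0.27 with an estimated correlation), 30 of 35 members above 0, and 10 higher adjusted over the list alone. Over all genes 1 rose, ADM, a peptide gene induced by hypoxia and not a glycolytic enzyme. Its set medians were 0.01, 0.28 and 0.68. Fatty acid synthesis and oxidation was not called in the average (median -0.10, adjusted p = 0.13, and adjusted p = 0.55 with an estimated correlation), though it was without Scramble library 3 (0.0055). Its set medians were -0.24, -0.11 and 0.15. Nuclear-encoded oxidative phosphorylation (median 0.03, adjusted p = 0.74) and ribosomal proteins (median 0.03, adjusted p = 0.45) were not called either, the ribosomal proteins except without Scramble library 1 (0.028). The set medians were 0, 0.05 and 0.07 for oxidative phosphorylation and -0.04, 0.13 and 0.02 for ribosomal proteins.

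Among the remaining lists, p53 targets were higher (median 0.32, adjusted p = 0.0043, and adjusted p = 0.54 with an estimated correlation; set medians 0.48, 0.32 and -0.06), with 0 of 33 members called over all genes, 3 higher and 1 lower adjusted over the list alone, and no call without Scramble library 3 (0.14). MDM2, the ubiquitin ligase that degrades p53, was at 175 ± 32.0 CPM in Scramble and 330 ± 80.2 and 330 ± 76.6 CPM with the hairpins (SD, n = 3 each; adjusted p = 0.073). Megakaryocyte and platelet markers were lower (median -0.16, adjusted p = 0.036, and adjusted p = 0.27 with an estimated correlation; set medians -0.15, -0.25 and -0.20), where GATA2, a progenitor factor and no platelet product, was the 1 of 7 tested members that fell, 1 adjusted over the list alone. That call was lost without Scramble library 2 (0.092), shRNA 1 library 1 (0.066) or shRNA 2 library 1 (0.056). Apoptosis regulators of the BCL2 and IAP families (median 0.19, adjusted p = 0.11), STAT5 and cytokine receptor targets (adjusted p = 0.94) and the MLL fusion and stemness programme (median -0.16, adjusted p = 0.092) were not called. The last was called lower without Scramble library 2 (0.019), shRNA 1 library 3 (0.035) or shRNA 2 library 3 (0.034), and with no filter or the replicate block (adjusted p = 0.05 for each, just under the threshold before rounding). For the STAT5 list the median (-0.06) and the mean (0.18) differed in sign. The medians in sets 1, 2 and 3 were 0.05, 0.17 and -0.05 for apoptosis, -0.22, -0.04 and 0.07 for STAT5, and -0.09, -0.07 and -0.18 for MLL. Heat shock proteins (median -0.12, adjusted p = 0.15; set medians -0.07, 0.07 and -0.23) were called lower only without Scramble library 2 (0.015), while HSPA6, an inducible member with near-identical relatives, rose by 1.95 ± 0.33. Markers of other cell types, lymphoid (median 0.28, adjusted p = 0.28, 6 of 25 tested; set medians 0.10, 0.18 and 0.33) and adherent packaging-cell and stromal (median 0.35, adjusted p = 0.51, 5 of 21 tested; set medians 0.05, -0.16 and 0.49), were not called.

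**Figure D4:**
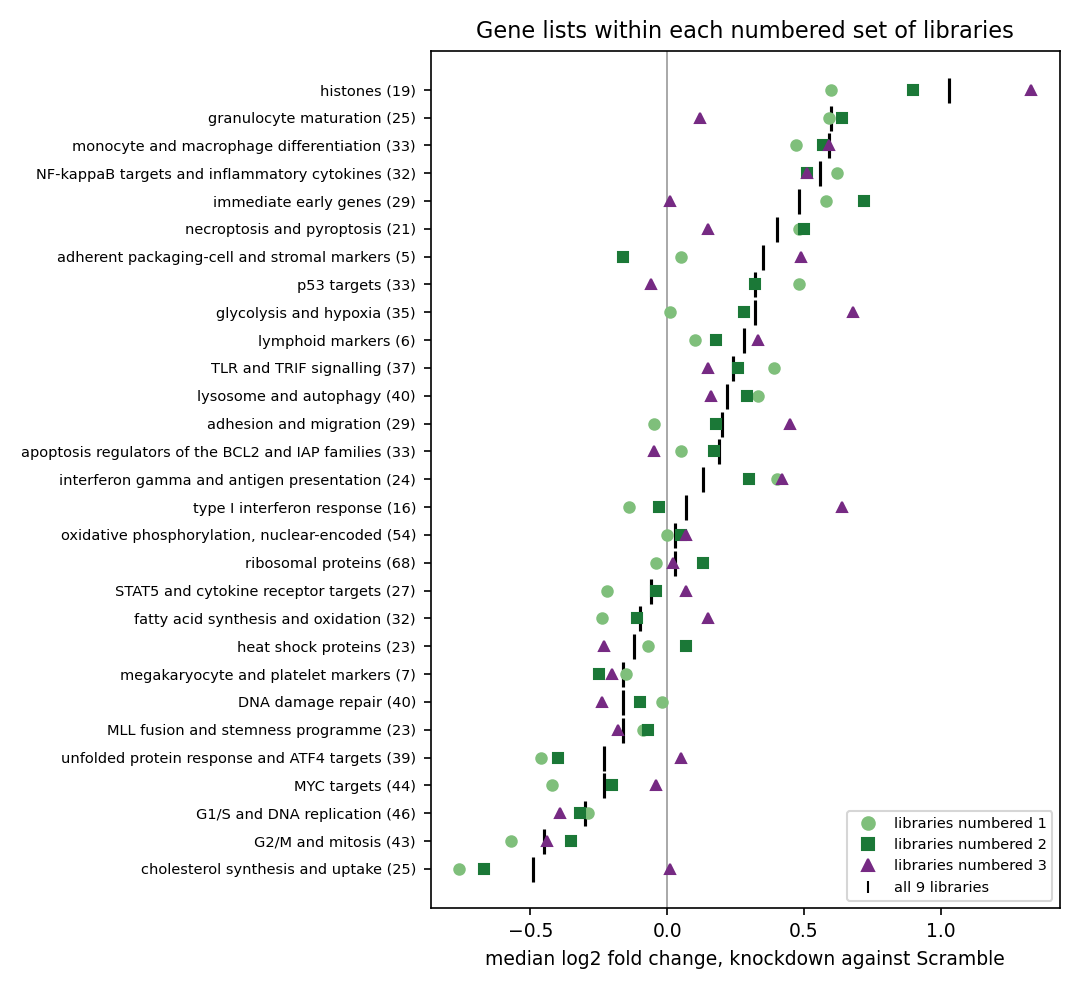
Median log2 fold change of each gene list, knockdown (mean of both hairpins) against Scramble, within the libraries numbered 1, 2 and 3 and over all 9 libraries; the number after each name is the count of members tested. Cholesterol synthesis and uptake lies at -0.76, -0.67 and 0.01 in sets 1, 2 and 3, and G2/M and mitosis at -0.57, -0.35 and -0.44.

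The hairpins were also compared with each other. No gene passed edgeR's test of shRNA 2 against shRNA 1 (0 genes, with 70 at an unadjusted p under 0.05), DESeq2 called 1 and limma-voom 0. With the replicate number as a block edgeR called 0 genes too, with 226 at an unadjusted p under 0.05. Both counts lie well below chance, since 4.64% of 11886 unchanged genes in simulated libraries had an unadjusted p under 0.05. Libraries of both hairpins with the same number deviated together at 0.73, 0.57 and 0.87, which the test without the block ignores. That can overstate the spread between the hairpins, so the 0 does not show that they act alike. MPEG1 was at 26.8 ± 8.63 CPM with shRNA 1 and 52.2 ± 2.66 CPM with shRNA 2 (SD, n = 3 each), and TICAM1 differed by 0.01 ± 0.19 (SE) on the log2 scale, both without a call. Camera with a preset correlation called 6 of 29 lists, 1 higher and 5 lower with shRNA 2, and none with an estimated correlation (smallest adjusted p = 0.89). Nuclear-encoded oxidative phosphorylation was lower with shRNA 2 (median -0.09, adjusted p = 3.4e-07, and adjusted p = 0.89 with an estimated correlation; 0 of 54 members called). Immediate early genes were lower with shRNA 2 as well (median -0.18, adjusted p = 0.0041, and adjusted p = 0.89 with an estimated correlation; 0 of 29 members called), a call lost without shRNA 1 library 1 (0.92). Toll-like receptor and TRIF signalling was higher and granulocyte maturation, ATF4 targets and fatty acid metabolism were lower with shRNA 2 (adjusted p = 0.029 for each, and adjusted p = 0.96 for each with an estimated correlation). The first and the ATF4 call were lost without shRNA 1 library 3 (1 and 0.49) or shRNA 2 library 1 (0.73 for each) or 2 (0.28 for each). The granulocyte call was lost without shRNA 1 library 1 (0.92) or 2 (0.61) or shRNA 2 library 3 (0.18), and the fatty acid call without shRNA 1 library 1 (0.2) or 2 (0.052) or shRNA 2 library 1 (0.35). MYC targets, not called here (adjusted p = 0.061), were called lower with the replicate block (adjusted p = 0.0072, and adjusted p = 0.84 with an estimated correlation). In the libraries numbered 1 and 2 alone, 5 lists not called in all 9 libraries were called lower with shRNA 2: cholesterol synthesis and uptake (median -0.25, adjusted p = 1.3e-13 against 0.09), MYC targets (5.7e-05), G1/S and DNA replication (0.031), STAT5 targets (0.031) and heat shock proteins (0.028). With an estimated correlation the adjusted p was 0.78 for each of the 5.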

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

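The tests of depth, of swapped libraries, of an additive shift, of handling by number, and those on the third set's sterol and ATF4 genes were chosen only after the result was seen, as were the interaction itself and the regroupings within numbered sets.

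The effect of knockdown differed between the third libraries and the first and second in 2896 of 11984 genes by an interaction test in edgeR, with 1365 higher and 1531 lower in the third set, and 4372 at an unadjusted p under 0.05. The difference rests on 1 Scramble library in the third set. Both hairpins were pooled as 1 knockdown group, and every library was counted as independent. Libraries of both hairpins with the same number deviated together at 0.57 to 0.87, so the count may be too high. Among genes chosen after their values were seen, the log2 difference of FOS, an immediate early transcription factor, was 4.18, 3.74 and -1.02 in sets 1, 2 and 3, that of CHAC1, an ATF4 target that degrades glutathione, -3.94, -3.84 and 0.20, and that of IFIT2, an interferon-induced gene, -2.05, -1.74 and 3.37. Lists with a higher effect in the third set included ATF4 targets (adjusted p = 2.5e-09, and 0.38 with an estimated correlation), cholesterol synthesis and uptake (adjusted p = 5.5e-09, and 0.57) and glycolysis and hypoxia (adjusted p = 5.9e-06, and 0.75).

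The third library of each group stood apart from the first and second. Depth is argued against, since 0 of the third libraries lay outside the range of the other 6, and so are GC content and gene length, which explained an R2 of 0.007 of the shift across genes. A swap between knockdown and Scramble is argued against by TICAM1, which was 10.3 CPM higher in the third Scramble library than in the higher of the knockdown libraries with that number. A single additive shift common to all groups would move Scramble as it moves the hairpins, but these shifts correlated at no more than 0.32 across genes. A different day, culture state or set of cells may remain, and the labels give nothing to test it by.

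The fold changes of both hairpins resembled each other. Against different Scramble libraries their covariance was 65.8% of that against the same ones, which argues against shared Scramble libraries as the whole source, though part may come from them. Within sets 1 and 2, handling peculiar to each number is argued against as the whole source by a correlation of 0.71 between shRNA 1 in set 1 and shRNA 2 in set 2. That correlation cannot argue against handling common to sets 1 and 2, whose knockdown libraries lay together on the first principal component. Between the third set and these, different hairpins correlated at 0.04 to 0.20, so for the third set shared handling stays open. An effect of lower TICAM1, or a response to any active hairpin, stays open, since Scramble was the only control. TICAM1 differed most in set 3 (log2 difference -1.04, against -0.47 and -0.42 in sets 1 and 2), whose fold changes resembled those of the other sets little. The G2/M and mitosis list was lower in every set (medians -0.57, -0.35 and -0.44). Across genes the response thus did not follow the size of the TICAM1 fall, with 1 Scramble library per set.

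Cholesterol and ATF4 lists were lower in sets 1 and 2 and not in set 3. For the cholesterol list this is consistent with a low level in the third Scramble library: over the 21 of 25 members lowered in sets 1 and 2, that library lay 0.93 of the way to the knockdown level (median, quartiles 0.84 and 1.22). Over the same members the third knockdown libraries lay 0.12 of the way back to Scramble (quartiles -0.09 and 0.23), and over all 25 their mean log2 CPM was 6.14 and 6.35, against 5.93 to 6.23 in the other knockdown libraries and 6.85, 6.78 and 6.12 in Scramble libraries 1, 2 and 3, which argues against a missing fall as the whole source, though shRNA 2 library 3 lay above the other knockdown libraries. For the ATF4 list the mean log2 CPM goes with a missing fall, at 6.48, 6.42 and 6.30 in Scramble libraries 1, 2 and 3. It was between 5.70 and 5.85 in the first and second knockdown libraries, and 6.47 and 6.34 in the third ones. Over its 26 lowered members of 39 the third Scramble library lay at -0.07 of the way (quartiles -0.37 and 1) and the third knockdown libraries at 0.94 of the way back (quartiles 0.49 and 1.29), so the spread between members leaves both explanations open, and 1 Scramble library stands for the third set.

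Other splits of the samples were counted for each result. For shRNA 1, 1 of 10 splits reached the real 8 genes and the highest other gave 0, for shRNA 2, 1 of 10 reached 21 and the highest other gave 0, and for shRNA 2 against shRNA 1, 10 of 10 reached 0 with a highest other of 0; these splits are too few for a share under 0.05. For shRNA 1, whose libraries correlated weakly by number with Scramble, the splits that part as many pairs as the real one also gave 0. In the average 1 of 100 splits reached 146 genes, with a highest other of 18. For genes called in the same direction 1 of 100 reached 7, with a highest other of 0. These drawn splits do not keep the numbered sets together. That can widen the spread within groups and lower their counts, so they do not exclude chance. Of 100 regroupings that keep 1 library of each number in each group, 1 reached 146 genes, with a highest other of 114. For the same direction 1 reached 7, with a highest other of 3. The 3 others with the real Scramble libraries, which exchange the hairpins alone, gave 101, 109 and 114 genes in the average, and the rest gave 0. Within the numbered sets only the real choice of Scramble libraries thus gave genes in the average, with 1 Scramble library per set. For the lists called in the average 16 of 100 splits reached 19, with a highest other of 23, as did 13 of 100 regroupings within numbered sets, with a highest other of 20, so chance was not excluded. In place of shRNA 2 against Scramble, 3 of the drawn splits gave more genes than the real one, up to 1276, and in place of shRNA 2 against shRNA 1 they gave up to 2883, which points to a structure of the samples.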

How the results depend on the processing

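The term for the third libraries, the first and second libraries alone, the estimated correlation combined with these or with the block, and the permutation of list means were chosen only after the result was seen.

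RLE scaling lost 1 of the 21 genes of shRNA 2 and 7 of the 146 of the average, which left 20 and 139, and changed no call of a named gene or list. The counts of genes for shRNA 1, shRNA 2, the average and the same direction were 423, 536, 888 and 324 with DESeq2, and 15, 39, 72 and 14 with limma-trend on log2(TPM + 1). With limma-voom they were 1 for shRNA 1, 4 for shRNA 2 and 1 for the same direction. With the third libraries as a batch term they were 940, 1268, 1866 and 792, and with the first and second libraries only 2529, 2875, 3516 and 2106. The first and second libraries of a group lay closer to each other than to the third, so these last counts may be too high. With only the 2 groups compared they were 0 for shRNA 1 and 0 for shRNA 2 (edgeR, 1336 and 1483 genes at an unadjusted p under 0.05). The average was 86 with no filter and 50 with at least a 2-fold change, which is a stricter threshold by construction. DESeq2 called 1 gene between the hairpins. For the other changes the cause was not tested.

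With the replicate number as a block the counts were 610, 909, 1370 and 527. Without it they were 8, 21, 146 and 7, so the counts depend strongly on this choice. Same-number libraries correlated with Scramble only weakly, at 0.14 to 0.19 for shRNA 1 and -0.02 to 0.18 for shRNA 2. A firm pairing with Scramble is thus shown for neither hairpin, while the third libraries stood apart in every group. The blocked counts of shRNA 2 and of the average are given here and not beside the results.

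Leaving out each library in turn gave 0 to 15 genes for shRNA 1, 0 to 36 for shRNA 2, 0 to 154 for the average and 0 to 10 for the same direction. The correlation of the fold changes was 0.662 with no filter and 0.707 with DESeq2, and 0.82 to 0.932 over single omissions; the cause was not tested.

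The TICAM1 log2 fold change kept its direction in every alternative run. It passed the threshold for shRNA 1 with the batch term (-0.66) and in the first and second libraries (-0.42), for shRNA 2 likewise (-0.64 and -0.52), and for the average with DESeq2 (-0.64), the block (-0.65), the batch term (-0.65) and the first and second libraries (-0.47). The cause was not tested. Over single omissions it was -0.79 to -0.46 for shRNA 1, and -0.71 to -0.55 for shRNA 2 and the average.

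Gene lists called for shRNA 1, shRNA 2, the average and between hairpins were 2, 2, 2 and 0 with an estimated correlation and 3, 3, 3 and 0 with fry. They were 0 in all 4 with an estimated correlation in the first and second libraries, and 4, 0, 0 and 0 with the block and an estimated correlation. fry's mixed test, which ignores direction, gave 9, 17, 21 and 0. Between hairpins no filter gave 3 and the first and second libraries 11. Over single omissions the lists called numbered 12 to 22, 15 to 21, 16 to 21 and 5 to 13. The adhesion and migration list reversed without Scramble library 3, with an adjusted p of 0.88 for shRNA 2 (range 0.00024 to 0.88) and 0.82 for the average (range 0.00022 to 0.82). The cause was not tested.

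Of 135 results for named genes, 57 that had missed the threshold passed with DESeq2, 54 with the block, 66 with the batch term and 65 in the first and second libraries. In turn 16 no longer passed with limma-voom and 1 with no filter. Over single omissions, 6 (without shRNA 1 library 3) to 48 (without Scramble library 2 or shRNA 1 library 1 or 2) no longer passed. Some passed newly without Scramble library 3 (3), shRNA 1 library 3 (5) or shRNA 2 library 3 (3). A pseudocount of 0.1 and a filter on the mean apply to files with normalized values alone and were not run. At this depth and spread, 6% to 10% of genes changed 1.5-fold were recovered in simulated data, so most changes of that size would be missed.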

Other observations

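The test of the hallmark sets was added after the data were seen.

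In the average camera with a preset correlation called 20 of the 50 hallmark sets in the deposited annotation, 12 higher and 8 lower, and 0 with an estimated correlation. G2M checkpoint genes were lower (median log2 fold change -0.27, adjusted p = 1e-18, and 0.46 with an estimated correlation), interferon gamma response genes higher (median 0.15, adjusted p = 5.5e-05, and 0.53), interferon alpha response genes higher (median 0.10, adjusted p = 0.021, and 0.53; with shRNA 1 and shRNA 2 alone 0.028 and 0.023, and 0.62 and 0.52) and TNF alpha signalling through NF-kappaB higher (median 0.28, adjusted p = 0.0002, and 0.76). The cholesterol homeostasis set had medians of -0.32, -0.34 and 0.15 in sets 1, 2 and 3.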
